A study of Mus musculus with 4 samples.

How the data were processed

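The study sorted cells of the mouse femoral periosteum, the membrane that covers bone, by a lineage label. Per the labels' protocols, the mice carried a tamoxifen-inducible Cre recombinase driven from the Sox9 locus and a Cre-dependent TdTomato reporter, so that cells expressing Sox9 at the time of tamoxifen, and their descendants, turned red. The animals received 3 injections of 100 µL tamoxifen at 20 mg/mL, 48 h apart, and intact femora were taken 2 weeks after the last one. Diaphyses were digested with liberase at 100 µg/mL for 2 h, and TdTomato-positive and TdTomato-negative cells were sorted by flow cytometry, per the labels' protocols. About 10000 cells of each population came from 18 femora of 9 mice in 2 collections. Libraries were made with a SMARTer low-input kit and sequenced as 75-nucleotide paired reads, per the labels' protocols. The labels give 4 samples in 2 groups, a TdTomato-positive and a TdTomato-negative sample from each collection. Each collection pooled mice, so the p-values measure at most the spread between these libraries, not that between mice.

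Per the submitters' processing notes, STAR and Partek were used with the mm10 build. Their versions are not given in the sources used here. The file used here is a table of the authors' own comparison of positive with negative cells over 47643 genes and 29 columns. Per the file headers it gives, for each gene, the group means of a normalized signal, its highest value and its sum over libraries as a score, and the difference of the group means on the natural log scale. The authors' deposited table also holds a ratio of group means, a signed fold change as a score, a p-value and a step-up FDR, from a lognormal model with shrinkage, per the file headers. The highest value and the sum are headed as raw reads but hold fractional values on the scale of the signal. The table carries no column per library.

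With 2 libraries per group, the 2 group means, the highest value and the log difference fix the 4 library values of a gene, and each of the 47643 genes had exactly 1 solution. The solved values matched reads divided by depth and by the genomic span of the gene (RPKM), plus an offset of 0.1, divided by depth and span once more. This scale, the offset and the depths were inferred from the values and are stated in no header. A column not used in the solution was compared with it: the Akaike criterion of the authors' model ran from -88.7 to 73.3 over genes, and stayed between 24.5 and 25.8 after 2 times the summed natural log of the solved values was subtracted. The implied depths were 32.0 and 41.6 M reads for the positive libraries and 17.0 and 74.0 M for the negative ones. The values here are RPKM per kilobase of genomic span, introns included, with the second scaling undone, so long genes with long introns have low values.

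The table does not say which of a group's 2 values belongs to which library. The assignment that gave whole reads was taken, within 0.01 reads plus 1e-07 of the reads, up to a tolerance of 0.05. Where only 1 value of a pair was whole, within 0.002 reads, or where the other assignment gave negative reads, that decided. Of 17077 genes with at least 10 reads in at least 2 libraries, 11674 (68.4%) were resolved in both groups. For the others both assignments were kept, and the text gives ranges that cover both. The fits took the assignment whose 2 libraries differ less, which put 84.4% of the depth of the negative library of 74.0 M reads in genes. The other assignment, taken for all unresolved genes at once, would put 216% there. It can therefore hold for single genes only. No value carries a collection number, so libraries are named by group and depth. On simulated data for all 47643 genes, 99.9% of the genes with whole reads and enough of them were resolved, all of them correctly. Of genes simulated with fractional reads, 17.0% were resolved, 98.3% of these correctly.

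The design fixed before the data were examined called for a count test, or limma on log2 values where only normalized values were deposited. The table holds neither counts nor library columns, and limma on recovered RPKM needs an assumed assignment for the unresolved genes. For these reasons the authors' deposited p-values and FDR were used as the main test of each gene, two-sided at an FDR of 0.05, which departs from the design. This choice was settled only after limma on log2(RPKM + 1), the test planned for normalized values, had been run and had called 0 genes, so the calls of both are given. The design planned camera on the log2 values for the gene lists, which moved to the authors' p along with the main test. Among the genes named, the authors' p followed the size of the fold closely and the spread of the single gene little. In the authors' deposited table Gas1 and Notum, with log2 folds of 4.35 and 4.31, had a p of 0.00366 and 0.00274. Only Notum had both positive libraries above both negative ones. A small p, or a list that passed on it, need not mean that the libraries of a group lay close. Log2 folds are the authors' difference of natural logs, with the value of unread genes (-0.0283) subtracted, converted to log2. They lie on a log2(RPKM + 0.1) scale, need no assignment of libraries, and understate the change of low genes. Where a group had no reads, the log2 fold, and any median that includes it, depends on the offset. The authors' fold is a ratio of arithmetic means of the signal scaled a second time, so it differs from the log2 fold. Coordinates are those of the table on mm10. The 39106 gene identifiers shared with GENCODE M21 had the same chromosome, start and end there.

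Genes named in the text followed a rule set before the data were examined. Sox9 was always named. Then came up to 12 genes per direction that passed the FDR, with a mean of at least 10 RPKM in the higher group and the same direction in both collections, without predicted or clone names and immunoglobulin or T-cell receptor segments, by largest fold. Places left were filled by the smallest unadjusted p, as genes that do not pass. Because values carry no collection number, the same direction was read as both libraries of one group above both of the other under either assignment. For each gene list, the 4 members with the smallest p could be named, in that order, and any member of the chondrocyte list.

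The 35 gene lists, also fixed before the data were examined, cover chondrocyte, hypertrophic chondrocyte, osteoblast, osteocyte, skeletal progenitor, tendon and matrix genes, signalling pathways, markers of blood, vessel, muscle, fat and nerve cells, and genes of stress, proliferation, metabolism and translation. Of 666 symbols, 665 were matched in the table, 3 of them through older symbols in a RefSeq table of GRCm38.p6, and a pattern gave 80 ribosomal protein genes. Each list was tested with camera in limma, with a preset correlation of 0.01, on the signed z of the authors' p over the 17077 genes with enough reads, with Benjamini-Hochberg adjustment over the 34 lists with at least 5 such members. A member counts as higher or lower by the sign of its log2 fold.

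Alternatives were other filters of the genes adjusted over, limma with pseudocounts of 1, 0.1 and 5, quantile normalization, limma-voom on the recovered reads, a test against a fold of 2, depths without mitochondrial, ribosomal protein and haemoglobin genes, each library left out in turn, both possible pairings of positive and negative libraries as a block, the other assignment of unresolved genes, resolved genes only, an estimated correlation, fry, and lists without shared members. On data simulated for the 3351 resolved genes with at least 1 RPKM in 2 libraries, limma called 100% of genes changed 16-fold and 100% of those changed 4-fold at a dispersion of 0.05. At a dispersion of 0.5 it called 66% and 4%. Versions were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.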

Results

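RNA was profiled in 4 libraries of sorted periosteal cells from mouse femora, 2 from cells that carried the Sox9-lineage TdTomato label and 2 from cells that did not. The implied depth was 32.0 and 41.6 M reads in the positive libraries and 17.0 and 74.0 M in the negative ones. Of the 47643 genes listed, 26627 had reads in at least 1 library and 17077 had at least 10 reads in 2 or more. The comparison asks how periosteal cells with a history of Sox9 expression differ from the other cells released from the same bone surface.

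Sox9, the transcription factor of the chondrocyte lineage whose locus drives the label, was read at 16.4 and 4.51 RPKM in the positive libraries and at 3.32 and 0.0244 RPKM in the negative ones. These values rest on 2897 and 1038 reads against 312 and 10. Sox9 (chromosome 11, 112782224 to 112787760, mm10) had a log2 fold of 3.74, with both positive libraries above both negative ones. In the authors' deposited table its p was 0.0104 and its FDR 1.00, so the difference did not pass. Without the negative library of 74.0 M reads, its limma log2 fold on RPKM + 1 was 1.18, against 2.22 with all libraries. Which libraries were collected together is not recorded in the values, and with each possible pairing as a block on resolved genes the adjusted p of Sox9 in limma was 0.0485 and 0.963. Cells were labelled 2 weeks before harvest, so the Sox9 transcript at harvest need not follow the label, and the reporter transcript was not analysed here.

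A cartilage collagen, a chondrocyte protein and a bone protein rose in the TdTomato-positive cells. The genes that passed were Col2a1, the main fibrillar collagen of cartilage, Mia, a small secreted protein made by chondrocytes, and Bglap, which encodes the bone protein osteocalcin. The authors' deposited table lists Col2a1 at a fold of 229 (FDR 4.28e-05), Mia at 142 (FDR 0.0198) and Bglap at 14.0 (FDR 0.0198). It holds 3 genes under the FDR threshold, all higher in positive cells, and 0 lower. At an unadjusted p below 0.05 the authors' deposited table holds 426 genes, 285 of them higher and 141 lower. Among the genes named, these p-values followed the size of the fold more than the spread between a gene's libraries. Limma on log2 of the recovered RPKM + 1, the test planned before the data were examined, called 0 genes in either direction, with 722 of 6860 genes at an unadjusted p below 0.05. The authors' test was taken as the main one after that result was seen. For unresolved genes this limma fit took the assignment whose 2 libraries differ less, which narrows the spread and can lower p. On resolved genes only, 236 of 3351 had an unadjusted p below 0.05. On 3351 resolved genes, limma with the possible pairings of libraries as a block called 28 genes higher and 20 lower with 1 pairing, and 0 in either direction with the other, which had 90 genes at an unadjusted p below 0.05. Col2a1, Mia and Bglap had unresolved positive values and were not among these genes, so the pairings did not retest them.

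Col2a1 (ENSMUSG00000022483.16, chromosome 15, 97975602 to 98004695) reached 52.8 to 123 RPKM in the positive libraries under either assignment. The negative libraries held 108 and 5 reads of it, or 0.219 and 0.00232 RPKM. Mia (ENSMUSG00000089661.9, chromosome 7, 27179742 to 27181157) lay between 5.19 and 35.9 RPKM in the positive libraries. It had 0 reads in both negative libraries, so its fold depends on the offset. Bglap (ENSMUSG00000074483.2, chromosome 3, 88383501 to 88384464) lay between 738 and 2766 RPKM in positive cells and at most at 471 RPKM in negative cells. Bglap and its neighbour Bglap2 are near-identical copies whose reads the counting could split, so their separate values are uncertain.

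Of the genes with a mean of at least 10 RPKM in positive cells and both positive libraries above both negative ones, the 9 next by p in the positive direction did not pass. Chad, a cartilage matrix protein that binds cells, was at 825 and 89.3 RPKM in the positive libraries and at 31.9 and 0.0762 RPKM in the negative ones. Comp, a cartilage oligomeric matrix protein, was at 199 and 43.9 RPKM against 13.7 and 0.0175 RPKM. Gpha2, a glycoprotein hormone subunit, was at 18.0 and 8.88 RPKM against 0.594 and 0.0195 RPKM. Clu, a secreted chaperone, was at 56.2 and 10.1 RPKM against 2.44 and 0.0951 RPKM. Log2 folds of the others were 6.98 for Bglap2, 5.83 for Sparc, which encodes osteonectin, 5.62 for Mgp, an inhibitor of calcification, 5.13 for Cytl1 and 5.04 for Timp1, an inhibitor of metalloproteinases.

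**Figure D1:**
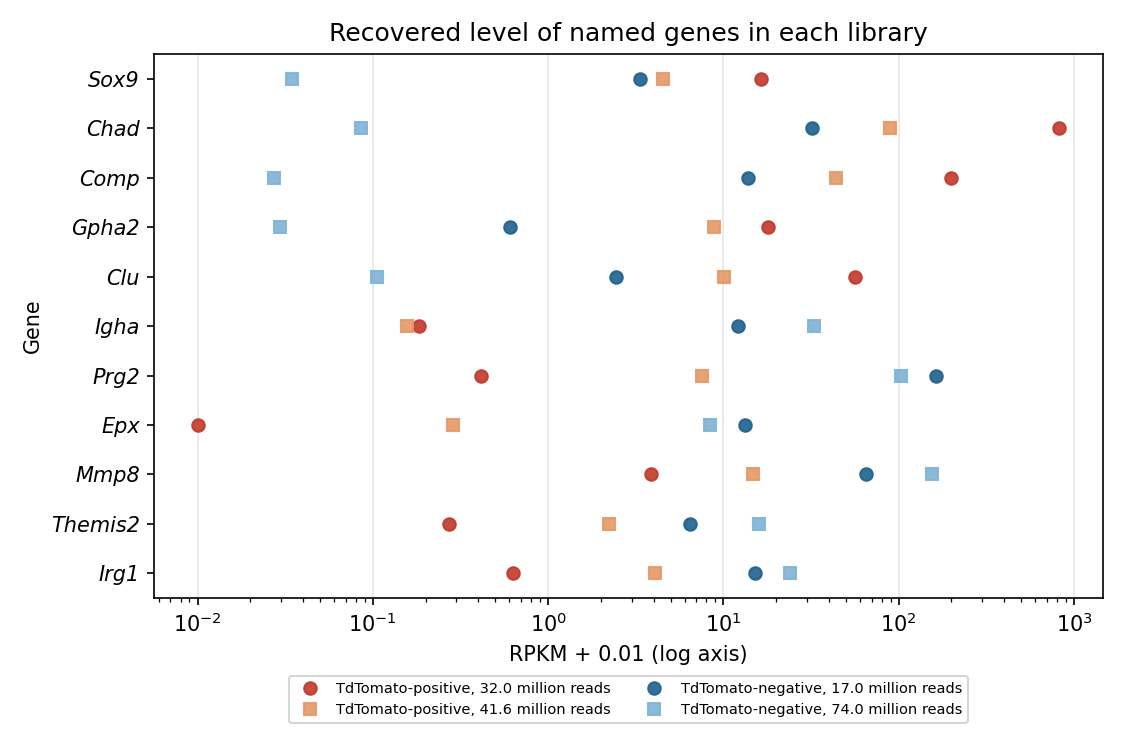
RPKM + 0.01 on a log axis for the named genes whose values could be assigned in all 4 libraries, with red and orange points for the TdTomato-positive libraries and blue points for the TdTomato-negative ones. Chad spans 825 RPKM in 1 positive library to 0.0762 RPKM in the negative library of 74.0 M reads, while Prg2 is at 164 and 103 RPKM in the negative libraries and at 7.57 RPKM or less in the positive ones.

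In the negative direction no gene passed. Prg2 and Epx encode eosinophil granule proteins, the major basic protein and eosinophil peroxidase. Prg2 was at 164 and 103 RPKM in the negative libraries and at 0.405 and 7.57 RPKM in the positive ones. Epx was at 13.3 and 8.38 RPKM in negative cells against 0 and 0.275 RPKM in positive cells. Igha, the constant region of immunoglobulin A, was at 12.2 and 32.9 RPKM against 0.174 and 0.147 RPKM. In the authors' deposited table the FDR was 0.0953 for Igha, 0.170 for Prg2 and 0.185 for Epx. Mmp8, the neutrophil collagenase, was at 65.4 and 154 RPKM in negative cells and at 3.86 and 14.8 RPKM in positive cells. Log2 folds were -5.07 for Ear6, an eosinophil ribonuclease, -3.61 for Cd300lb, -3.60 for Trem1, -3.49 for Mmp9, -3.48 for Themis2, -3.46 for Irg1, -3.39 for Cxcr2 and -3.32 for Pram1.

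The chondrocyte list rose as a group. Of its 22 measured members 21 were higher in positive cells, with a median log2 fold of 3.49 (camera in limma, adjusted p = 5.81e-56; adjusted p = 0.608 with an estimated correlation). Col2a1 passed over all genes, and 15 members, all higher, passed when adjusted over the list alone. Among them, Col9a2, a chain of the cartilage collagen IX, had 3 and 21 reads in the negative libraries and 6.31 to 11.3 RPKM in the positive ones. Snorc, listed under its older name 3110079O15Rik, had 502 and 3576 reads in the positive libraries and 0 in both negative ones. Acan, the large proteoglycan of cartilage, was at 1.51 and 0.785 RPKM against 0.0688 and 0 RPKM. Sox5 and Sox6, partners of Sox9 in chondrocytes, had log2 folds of 0.07 and -0.09. They reached at most 0.0187 and 0.0313 RPKM in any library, below the offset of 0.1, which holds such folds near 0. Sox5 had 569 and 9 reads in the positive libraries and 125 and 41 in the negative ones. Whether these 2 genes differ is therefore not settled.

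Genes of hypertrophic cartilage rose as a list too, with 7 of 9 members higher and a median log2 fold of 2.40 (camera in limma, adjusted p = 1.38e-06; adjusted p = 0.608 with an estimated correlation). None of them passed over all genes or when adjusted over the list alone, 0 in each case. Panx3, a channel protein of prehypertrophic cartilage, had 80 and 1141 reads in the positive libraries and 0 and 0 in the negative ones. Mmp13, a collagenase, was at 19.4 and 5.46 RPKM against 4.11 and 0.121 RPKM. Alpl, Sp7 and Pth1r of this list are also on the osteoblast list, Mmp13 on that of matrix proteases and Vegfa on that of angiogenic factors. The rise is therefore not independent of those lists, and the result without shared members is not reported here.

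The osteoblast list rose, with 18 of 18 members higher and a median log2 fold of 3.35 (camera in limma, adjusted p = 1.60e-32; adjusted p = 0.616 with an estimated correlation). Bglap passed over all genes, and 10 members passed when adjusted over the list alone, led by Bglap, Bglap2, Sparc and Col1a1, the main collagen of bone. Both positive libraries lay above both negative ones under either assignment in 11 of the 18, and the 7 resolved members had a median of 10.6 and 2.15 RPKM in the positive libraries and 2.44 and 0.0137 RPKM in the negative ones. All 8 measured osteocyte genes were higher, with a median log2 fold of 2.22 (camera in limma, adjusted p = 5.42e-08; adjusted p = 0.608 with an estimated correlation). None passed singly, with 0 members when adjusted over the list alone. Dmp1, a matrix protein of osteocytes, was at 4.74 RPKM at most in positive cells and at 0.800 RPKM at most in negative cells. Skeletal progenitor genes, 21 of 22 higher, had a median log2 fold of 1.26 (camera in limma, adjusted p = 1.91e-08; adjusted p = 0.616 with an estimated correlation), and 0 members passed when adjusted over the list alone. Postn, which encodes periostin, had 10 reads in the negative library of 74.0 M reads but 5598 reads in that of 17.0 M reads, where its level lay above the lowest positive value of 7.83 RPKM. Ctsk, a cathepsin of osteoclasts and periosteal cells, was at 28.7 and 9.54 RPKM against 5.72 and 0.152 RPKM. In 1 of the 22 progenitor genes both positive libraries lay above both negative ones, and the limma median of 7 resolved members was 0.22 without the positive library of 32.0 M reads and 0.26 without the negative library of 74.0 M reads, against 0.95 with all libraries. The median of the 14 resolved progenitor genes was 0.873 RPKM in the negative library of 17.0 M reads and 0.515 RPKM in the positive library of 41.6 M reads.

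Connective tissue genes moved in the same direction. All 14 tendon and fibroblast genes were higher, with a median log2 fold of 3.02 (camera in limma, adjusted p = 1.63e-19; adjusted p = 0.616 with an estimated correlation), and 5 passed when adjusted over the list alone. Fmod and Thbs4, matrix proteins of tendon, had log2 folds of 4.97 and 4.19. Scx, the tendon transcription factor, was at 51.2 and 7.59 RPKM in the positive libraries and at 10.2 and 0.0200 RPKM in the negative ones, so that the groups overlapped. Tnmd, a tendon membrane protein, was at 21.1 and 6.34 RPKM against 4.98 and 0.00185 RPKM. All 30 fibrillar collagen and matrix genes were higher, with a median log2 fold of 3.23 (camera in limma, adjusted p = 7.61e-47; adjusted p = 0.616 with an estimated correlation), and 16 passed when adjusted over the list alone. Of 20 matrix proteases and inhibitors 18 were higher, with a median log2 fold of 1.95 (camera in limma, adjusted p = 4.96e-11; adjusted p = 0.616 with an estimated correlation). Timp1 and Mmp2 were the 2 that passed when adjusted over the list alone. Most of these genes were not separated by library: both positive libraries lay above both negative ones under either assignment in 2 of 14 tendon genes, 4 of 30 collagen and matrix genes and 5 of 20 proteases and inhibitors. The median of resolved tendon genes was 5.19 RPKM in the negative library of 17.0 M reads and 4.25 RPKM in the positive library of 41.6 M reads. In the same order it was 5.05 and 1.49 RPKM for resolved collagen and matrix genes and 0.707 and 0.243 RPKM for resolved proteases and inhibitors. Without the negative library of 74.0 M reads the limma median of 7 resolved members was 0.55 for tendon and 0.27 for collagen and matrix genes, and without the positive library of 32.0 M reads 0.74 and 0.72, against 2.09 and 1.68 with all libraries.

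Signalling genes were also higher as lists, with smaller medians. Their levels were low: resolved Wnt genes had medians of 0.351 and 0.129 RPKM in the positive libraries and 0.123 and 0.0250 RPKM in the negative ones. Since the offset of 0.1 understates the change of low genes, these medians do not show a smaller change than in other lists. Of 40 Wnt pathway genes 36 were higher, with a median log2 fold of 0.90 (camera in limma, adjusted p = 7.93e-09), and of 40 BMP and TGF-beta genes 37 were higher, with a median of 0.76 (adjusted p = 1.51e-05). Of 28 FGF, IGF and PTH genes 24 were higher, with a median of 1.08 (camera in limma, adjusted p = 2.94e-10), and of 15 hedgehog genes 13 were higher, with a median of 0.63 (adjusted p = 0.00616). With an estimated correlation the adjusted p was 0.616 for each of these 4 lists. Without the negative library of 74.0 M reads the limma medians of resolved members were 0.61 for Wnt, 0.23 for BMP and TGF-beta and 0.36 for FGF, IGF and PTH genes, and without the positive library of 32.0 M reads 0.78, 0.22 and 0.28, against 1.18, 0.70 and 1.04 with all libraries. No member passed when adjusted over the list alone, 0 in all 4. Resolved members had a higher median in the negative library of 17.0 M reads than in the positive library of 41.6 M reads for BMP and TGF-beta genes (0.330 and 0.224 RPKM), FGF, IGF and PTH genes (0.406 and 0.211 RPKM) and hedgehog genes (0.103 and 0.0738 RPKM). Notum, a secreted Wnt inhibitor, lay at 1.36 to 3.03 RPKM in positive cells and had 2 and 0 reads in negative cells. Of 18 Notch genes 11 were higher, with a median of 0.13 and a mean of 0.08 log2, while the camera test pointed downward (camera in limma, adjusted p = 0.958).

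The pan-leukocyte, neutrophil, lymphocyte, mast cell and erythroid lists fell in the positive cells, while platelet and macrophage genes did not. All 18 pan-leukocyte genes were lower, with a median log2 fold of -1.30 (camera in limma, adjusted p = 1.45e-08; adjusted p = 0.608 with an estimated correlation). All 20 neutrophil genes were lower, with a median of -1.32 (camera in limma, adjusted p = 3.74e-09; adjusted p = 0.608 with an estimated correlation). The 8 resolved neutrophil genes had a median of 9.89 and 54.2 RPKM in the positive libraries and 52.5 and 110.0 RPKM in the negative ones, so the positive library of 41.6 M reads held neutrophil transcripts at the level of a negative library. Resolved pan-leukocyte and B-cell genes had medians of 5.75 and 0.721 RPKM in that positive library and of 4.26 and 0.636 RPKM in the negative library of 17.0 M reads. Of 20 B-cell genes 17 were lower, with a median of -0.98 (camera in limma, adjusted p = 2.75e-06; adjusted p = 0.616 with an estimated correlation). Jchain, the joining chain of secreted antibodies, was the 1 gene that passed when adjusted over the list alone, with 44 and 29 reads in positive cells. Medians of the pan-leukocyte, neutrophil and B-cell lists depended on which library was left out. On limma values of resolved members with at least 1 RPKM in 2 libraries, the medians without the positive library of 32.0 M reads were -0.13 for pan-leukocyte, 0.28 for neutrophil and -0.19 for B-cell genes. Without the negative library of 74.0 M reads they were -0.42, -0.44 and 0.59, against -0.85, -0.80 and -1.21 with all libraries. They lay farther from 0 without the negative library of 17.0 M reads (-1.28, -1.17 and -2.94) and without the positive library of 41.6 M reads (-1.63, -2.07 and -2.48).

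Lists of T and NK, mast and erythroid cells were lower as well, and so were cell cycle genes. All 18 T and NK cell genes had a lower level, with a median log2 fold of -1.34 (camera in limma, adjusted p = 2.41e-07; adjusted p = 0.608 with an estimated correlation), and Cd3e was at 0 and 0.00443 RPKM in positive cells against 0.576 and 0.579 RPKM. Over the 6 resolved T and NK cell genes with at least 1 RPKM in 2 libraries, the limma median was -0.44, against 0.58 without the positive library of 32.0 M reads and 0.03 without the negative library of 74.0 M reads. All 10 mast cell and basophil genes were lower, with a median of -3.09 (camera in limma, adjusted p = 8.12e-16; adjusted p = 0.608 with an estimated correlation). Tpsb2, a mast cell tryptase, was at 0 and 0.0622 RPKM against 10.9 and 0.105 RPKM, and Cpa3, a mast cell carboxypeptidase, was at 0 and 0.0805 RPKM against 1.76 and 0.906 RPKM. All 16 erythroid genes were lower, with a median of -1.38 (camera in limma, adjusted p = 1.41e-08; adjusted p = 0.608 with an estimated correlation). Cell cycle genes, lower in 29 of 30 cases, had a median of -1.56 (camera in limma, adjusted p = 6.90e-12; adjusted p = 0.616 with an estimated correlation). Without the negative library of 74.0 M reads the limma medians were -0.08 for erythroid and -0.35 for cell cycle genes, and without the positive library of 32.0 M reads -0.19 and -0.24, against -1.01 and -1.05. Resolved erythroid and cell cycle genes had medians of 3.35 and 3.18 RPKM in the positive library of 41.6 M reads and of 1.36 and 1.85 RPKM in the negative library of 17.0 M reads. When adjusted over the list alone, 0 members of these 4 lists passed.

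**Figure D2:**
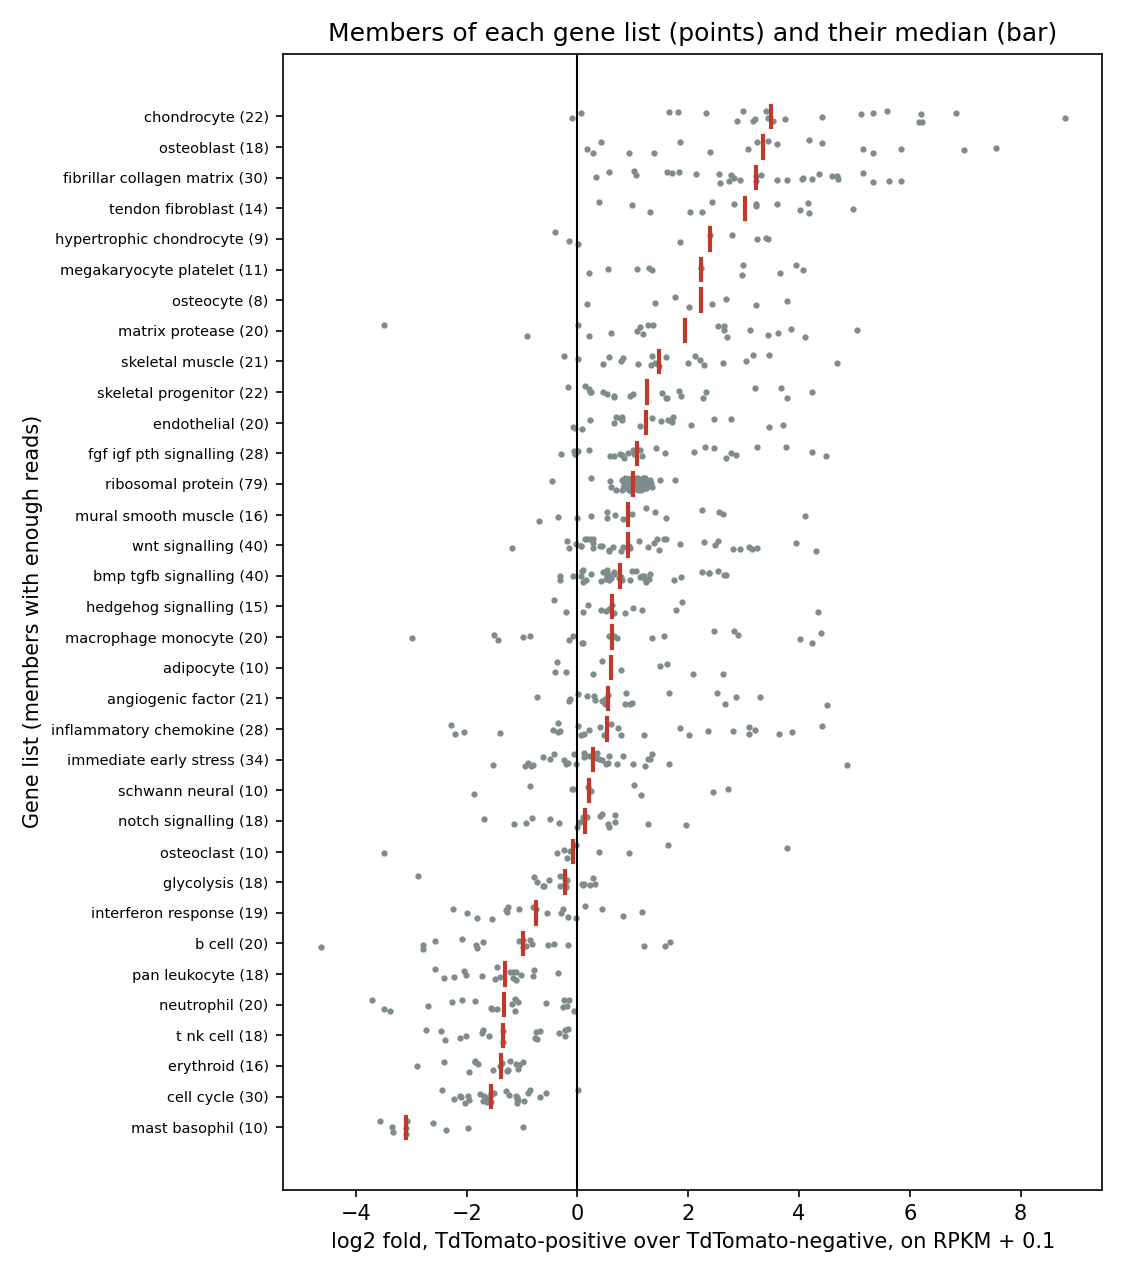
Each point is the log2 fold of 1 gene, TdTomato-positive over TdTomato-negative, on the scale of RPKM + 0.1, and each red bar is the median of its list. The chondrocyte list lies highest, with a median of 3.49 over 22 genes, and the mast cell and basophil list lowest, with a median of -3.09 over 10 genes.

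The list tests assume a correlation of 0.01 between genes, and with the correlation estimated from these 4 libraries 0 of the 34 lists passed. The test with the estimated correlation was run on log2(RPKM + 1) instead of the authors' p, so it differs in more than the correlation. Camera with the preset correlation on the same values still passed lists in both directions, as given below. With only 4 libraries, the test with an estimated correlation also has few residual degrees of freedom and little power. A list that failed it is therefore not shown to be unchanged. For hypertrophic, macrophage and interferon genes the estimated correlation was -0.0618, -0.00038 and 0.00195, below the preset 0.01. Correlation between genes therefore does not explain why these lists failed to pass. The estimate was 0.204 for chondrocyte, 0.732 for osteoblast, 0.972 for tendon, 0.922 for collagen and matrix and 0.356 for pan-leukocyte genes. Those estimates, rough with 4 libraries, lie well above 0.01. As far as they hold, the camera p-values of such lists at the preset correlation are too small. With limma on log2(RPKM + 1) in place of the authors' p, 13 lists were higher and 6 lower of 28, and on resolved genes 4 were higher and 5 lower of 19. From that last count, leaving out a library gave 0 higher and 0 lower without the negative library of 74.0 M reads, 2 and 0 without the positive library of 32.0 M reads, 6 and 7 without that of 41.6 M reads, and 10 and 5 without the negative library of 17.0 M reads. The 19 lists do not include the chondrocyte, hypertrophic, osteoblast, osteocyte, mast cell and platelet lists, among others. Those had fewer than 5 resolved members with at least 1 RPKM in 2 libraries, so leaving out a library did not test them. List medians lay farther from 0 in 19 of 19 lists without the negative library of 17.0 M reads and in 16 without the positive library of 41.6 M reads. Under either assignment, both positive libraries lay above both negative ones in 19 of 22 chondrocyte, 5 of 9 hypertrophic, 6 of 8 osteocyte, 16 of 40 Wnt, 9 of 40 BMP and TGF-beta, 9 of 28 FGF, IGF and PTH and 4 of 15 hedgehog genes. Both lay below in 3 of 18 pan-leukocyte, 7 of 20 neutrophil, 7 of 20 B-cell, 9 of 18 T and NK cell, 8 of 10 mast cell, 2 of 16 erythroid and 3 of 30 cell cycle genes.

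Among resolved genes, similarity between libraries did not follow the sort gate. Whole reads settled both groups for 8630 of these genes. Negative reads under the other assignment could settle a negative pair only where the library of 74.0 M reads had the low value. The set may therefore lean toward genes low in that library. Across 11674 resolved genes, which are not independent replicates, the log2 levels of the negative library of 17.0 M reads correlated with those of the positive libraries at Pearson r = 0.847 and 0.843, and with the other negative library at 0.781. The positive libraries correlated with each other at r = 0.800. The lowest value, 0.609, was between the negative library of 74.0 M reads and the positive library of 32.0 M reads. Of the resolved genes, 2269 had both positive libraries above both negative ones and 2099 had both below, together 37.4%, where chance gives 33.3%. Over all 17077 genes with enough reads, counting only those separated under either assignment, 2638 were higher and 2243 lower, together 28.6%.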

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

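The authors' FDR runs over all genes listed, and fewer genes adjusted over gave more calls. The authors' p adjusted over genes with at least 1 RPKM or at least 10 reads in 2 libraries, the other assignment, both pairings of libraries and resolved genes only were chosen after seeing the data. Limma on log2(RPKM + 1) was the planned test of genes, and camera on those values that of lists. Both became alternatives when the authors' p was settled on as the main test, after the limma result was seen. Its alternatives start from that fit, and voom, the pairings and the fits that leave out a library also keep to resolved genes. Col2a1, Mia and Bglap are not among the resolved genes. Adjusted over genes with reads, 5 genes were higher and 0 lower. Adjusted over genes with at least 10 reads in 2 libraries, 8 were higher and 2 lower. With at least 1 RPKM in 2 libraries, 11 were higher and 4 lower, and with a mean of at least 10 RPKM, 13 were higher and 3 lower. The 3 genes of the authors' FDR were among the calls of each of these filters except the last, which held 2 of them. Limma on values scaled by depth once called 0 genes in either direction under each of these settings: log2(RPKM + 1), pseudocounts of 0.1 and 5, quantile normalization, a fold above 2, all genes with reads, a mean of at least 10 RPKM, the other assignment, resolved genes, depths without mitochondrial, ribosomal protein and haemoglobin genes, voom, and each library left out (0 to 0). The number at an unadjusted p below 0.05 ran from 66 of 3351 genes in 1 of the fits that leave out a library to 1461 of 26627 with all genes with reads. The other assignment cannot hold for all unresolved genes at once, so its fit does not describe a possible set of values.

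Of the 34 lists, 21 were higher and 8 lower. On genes with a mean of at least 10 RPKM these were 7 and 4 of 18 lists with the authors' p, and 2 and 5 with limma. Lists higher numbered 13 with limma on log2(RPKM + 1) and with each of the other pseudocounts, and 12 with quantile normalization. Depths without mitochondrial, ribosomal protein and haemoglobin genes gave 12 and 5, resolved genes 4 and 5, and voom 9 and 5. Camera on log2(RPKM + 1) of the genes with enough reads gave 17 and 8 of 34. An estimated correlation and fry each gave 0 and 0, with a smallest adjusted p of 0.608 and 0.180. Leaving out 1 library gave 0 to 10 lists higher and 0 to 7 lower of 19, and without the negative library of 74.0 M reads it was 0 and 0. Fewer genes and lists were tested under the stricter filters and on resolved genes. The chondrocyte, osteoblast and mast cell lists were not among the 19. For the other changes the cause was not tested. In the fits that leave out a library, the lone library of its group is assumed to vary like the other pair.

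The log2 fold of Sox9 stayed above 0 under every alternative that gave a value, and short of the threshold under all but 1 of the pairings below, from 1.14 with a pseudocount of 5 to 6.54 with voom. The mean filter of 10 RPKM gave none. Single libraries were left out only for resolved genes with at least 1 RPKM in 2 libraries. Of the genes named and the leading members of lists among them, 5 changed direction: Ackr3 (-0.38 to 3.12), Gas1 (-0.36 to 6.14), Des (-0.44 to 2.95), Gzmb (-2.16 to 0.18) and Ppbp (-0.73 to 7.43). The limma median of the neutrophil list ran from -2.07 to 0.28 and that of the B-cell list from -2.94 to 0.59. The direction of the test also turned for the T and NK cell list (median -1.11 to 0.58), the mural list (-0.21 to 1.63) and the skeletal muscle list (-0.65 to 2.33). The test of the chemokine list turned downward with limma at a mean of at least 10 RPKM, at a median of 0.47. No value carries a collection number, so the planned block by collection could not be set, and both pairings were fitted as a replicate block with limma on 3351 resolved genes. The block that pairs the libraries of 32.0 and 17.0 M reads called 28 genes higher and 20 lower, with Sox9 at a log2 fold of 2.22 (adjusted p = 0.0485 in limma, with no gene below that value), and had 932 genes at an unadjusted p below 0.05. The other pairing called 0 and 0, with an adjusted p of 0.963 for Sox9 and 90 genes at an unadjusted p below 0.05, against 236 with no block. Both pairings gave 7 lists higher and 5 lower. Neither pairing can be preferred from these results. The count tests of edgeR and DESeq2 were not run, and limma-voom on recovered reads was the test of reads that was. Transcripts were not tested singly, since the table's entries are genes.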

Other observations

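The tests of explanations given after the lists were all chosen after the results were seen. Other cell types and programmes also differed by list. Platelet genes were higher in 11 of 11 cases, with a median log2 fold of 2.23 (camera in limma, adjusted p = 6.54e-10; adjusted p = 0.616 with an estimated correlation), and this lay mostly in 1 library. Pf4, a platelet chemokine, was at 41.4 to 629 RPKM in positive cells, and Gp1bb, a platelet receptor, was at 3.10 and 97.6 RPKM in the libraries of 32.0 and 41.6 M reads. Ppbp, another chemokine, was at 1.15 and 611 RPKM there and at 7.09 and 0.568 RPKM in the negative libraries, and its limma log2 fold was -0.73 without the library of 41.6 M reads. Macrophage and monocyte genes split: 13 of 20 were higher, with a median of 0.61 (camera in limma, adjusted p = 0.00254; adjusted p = 0.608 with an estimated correlation). Both positive libraries lay above both negative ones in 4 of 11 platelet and 6 of 20 macrophage genes. The complement genes C1qa, C1qb and C1qc were the 3 that passed when adjusted over the list alone. C1qa was at 43.8 and 87.6 RPKM in positive cells against 24.6 and 0.248 RPKM, whereas the integrin gene Itgam had a log2 fold of -2.99.

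Vessel and muscle genes were higher as lists. Endothelial genes (18 of 20 higher, median 1.24), mural genes (13 of 16, median 0.91) and skeletal muscle genes (20 of 21, median 1.48) had adjusted p = 7.30e-07, 0.000171 and 2.37e-10 with camera in limma, and adjusted p = 0.616, 0.686 and 0.678 with an estimated correlation. Myod1, a muscle transcription factor, was at 13.9 and 22.5 RPKM against 4.68 and 0 RPKM, and was the 1 muscle gene to pass when adjusted over the list alone. Without the negative library of 74.0 M reads the limma medians of resolved members were 0.19 for endothelial, -0.21 for mural and -0.65 for muscle genes, against 1.22, 0.83 and 0.78 with all libraries. Resolved mural, muscle and fat cell genes had medians of 1.02, 2.61 and 0.600 RPKM in the negative library of 17.0 M reads, above those of both positive libraries (at most 0.761, 1.64 and 0.481 RPKM). Without the positive library of 41.6 M reads the limma median of endothelial genes was 0.74, and without that of 32.0 M reads that of muscle genes was 0.45. The median of resolved endothelial genes was 0.660 RPKM in the negative library of 17.0 M reads and 0.606 RPKM in the positive library of 32.0 M reads. Ribosomal protein genes were higher in 78 of 79 cases, with a median of 1.00 (camera in limma, adjusted p = 3.15e-08; adjusted p = 0.608 with an estimated correlation), but both positive libraries lay above both negative ones in 4 of the 79. Chemokine genes (20 of 28 higher, median 0.54, adjusted p = 0.000335 with camera in limma), angiogenic factors (18 of 21, median 0.55, adjusted p = 7.68e-05) and fat cell genes (7 of 10, median 0.61, adjusted p = 0.0370) had adjusted p = 0.616 each with an estimated correlation. Both positive libraries lay above both negative ones in 5 of 20 endothelial, 4 of 16 mural, 2 of 21 muscle, 5 of 28 chemokine, 8 of 21 angiogenic and 2 of 10 fat cell genes. Mdk, the growth factor midkine, was the 1 angiogenic gene to pass when adjusted over the list alone. Interferon genes were lower in 15 of 19 cases, with a median of -0.76 (camera in limma, adjusted p = 0.00360; adjusted p = 0.608 with an estimated correlation). On resolved members, the limma median of interferon genes was -0.13 without the positive library of 32.0 M reads and -0.43 without the negative library of 74.0 M reads, against -0.70 with all libraries. That of chemokine genes was 0.03 without the negative library of 74.0 M reads and 0.02 without the positive library of 41.6 M reads, against 0.59. Glycolysis (median -0.23, adjusted p = 0.0981), Schwann cell (median 0.21, adjusted p = 0.268), immediate early (median 0.28, adjusted p = 0.305) and osteoclast genes (median -0.08 but mean 0.23, adjusted p = 0.702) did not pass camera in limma, although Cyr61 passed when adjusted over the immediate early list alone. The 15 mitochondrial genes matched had 0 members with enough reads.

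Most skeletal transcripts were lower in the deeper negative library than in the other. Of 74 members of the chondrocyte, osteoblast, matrix and tendon lists 67 were lower and 6 higher, and the median log2 difference between the negative libraries of 74.0 and 17.0 M reads was -3.77 (quartiles -6.41 and -1.29). Depth argues the other way, since 82.4% of them had fewer reads in the deeper library before any scaling. A smaller share of non-blood cells in that library is a candidate explanation: 55 endothelial, mural and muscle genes had a median log2 difference of -2.93, 54 of them lower, while all 7 resolved pan-leukocyte genes were higher, by a median of 1.15. It would not be the only difference, since 7 of 9 mast cell and basophil genes were lower there, with a median of -0.78 (quartiles -1.50 and -0.72). The labels name no difference between the collections, so none that the design gives was tested.

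The shallower negative library held skeletal transcripts, and TdTomato-positive cells carried over in the sort are a possible source. An even sample of such cells would bring all of their transcripts at 1 share, and Col2a1 was there at 0.414% of its lowest positive level. The 45 osteoblast, matrix and tendon genes with settled negative values were at a median of 23.5% of their highest positive level (quartiles 18.0% and 32.2%), and all 45 lay above the Col2a1 share. Of 18 chondrocyte genes, 12 lay above it, with a median of 4.22% over the 18. Col2a1 itself is counted among the 18 and could not lie above its own share. This argues against an even sample of the positive cells as the whole source. Carry-over of positive cells poor in Col2a1 stays open, and so do skeletal cells without the label, which were not tested.

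Few genes passed although folds were large, and the second scaling by depth may have widened the spread. Refitted with limma on the 11674 resolved genes, values scaled once gave 0 calls (687 genes at an unadjusted p below 0.05), and values scaled a second time gave 8 calls (215 genes). The adjusted and unadjusted counts ran in opposite directions, so the effect of the second scaling on the number of calls stays open. The authors' own model was not refitted.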
